A study of Mus musculus with 10 samples.

How the data were processed

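RNA was measured in 10 mouse tumors. Per the labels, chicken DF1 fibroblasts that produced an avian RCAS retrovirus were placed under the arachnoid membrane of newborn mice. The virus carried either YAP1-MAML2-v2 or NLS-2SA-YAP1, and the mice lacked Cdkn2a and expressed the viral receptor tv-a under Nestin control. Tumors were frozen and ground, and total RNA was made into stranded mRNA libraries that were pooled for sequencing. The libraries are YAP1-MAML2-v2 tumors (n = 7) and NLS-2SA-YAP1 tumors (n = 3). The group, the replicate number and the region were taken from the labels. By region there are 6 extra cranial libraries, 3 extra axial libraries and 1 intra ventricular library.

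Per the submitters' processing notes, reads were counted with HTSeq against mm10, with no versions. The aligner, the annotation, the strand setting and any later steps are not given in the sources used here. Each deposited file lists 16895 genes in the same order, with human-style symbols and whole numbers. Ignoring case, 15475 symbols (91.6%) match a mouse symbol of GENCODE M21, the mm10 annotation from which coordinates were taken. The mouse genes were therefore carried to human names by a step that is not stated, and genes without such a counterpart are not analysed here. How reads shared by near-identical genes were counted is not given in the sources used here.

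The deposited values were treated as estimated counts, not as raw counts. Each library holds 4.54 to 6.82 times as many genes at 1 as at 2. Among the 10505 genes with a median over 200, 251 values are 0, 219 are 1 and only 21 are 2. An adjustment that kept 0 and 1 and rescaled the other values would leave such files, but no label or header records one. The plan made before the data were examined had assumed raw counts. The values are whole already, so the planned count test was run on them without further rounding, and tests that do not need raw counts were added. Totals per library lie between 28001143 and 44544314. They are not sequencing depth, which is unknown where values are not plain read counts, so no counting intervals or detection floors are given. A fold between a value of 0 or 1 and a higher one has no clear meaning, and 1662 genes hold 0 or 1 in some library and over 100 in another. Of these, 1336 were among the genes tested.

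Genes were kept with filterByExpr by tumor group at a minimum count of 10, which left 13707 genes. Libraries were scaled by TMM. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with robust dispersion, fitted to all 10 libraries with construct and region as terms. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and 0.05 was the threshold. A log2 fold change between constructs is NLS-2SA-YAP1 minus YAP1-MAML2-v2, and between regions it is extra axial minus extra cranial. The intra ventricular library is fitted exactly by its own term, but still enters the gene filter and the scaling. Without it 13487 genes were tested, and the edgeR adjusted p of CHRDL1 and IGF2BP1 was 0.0295 in place of 0.0406. The interaction of construct and region was fitted to the libraries of the extra cranial and extra axial regions. CPM values were computed with edgeR from the deposited values and the TMM-scaled library totals, and log2 CPM used a prior count of 2.

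Gene lists (24, with 322 genes, of which 312 are in the files) were fixed before the data were examined. Lists with at least 3 tested members were tested with limma's camera (limma 3.58.1) on log2 CPM with the correlation between genes preset at 0.01. That held for 23 lists. The erythroid list had too few tested members. The 23 lists cover YAP1-TEAD targets, Hippo components, Notch, meningeal fibroblast, meningioma, cell cycle, AP-1, collagen, type I interferon, MHC class II and hypoxia genes. The others mark neurons, astrocytes, oligodendrocytes, choroid plexus and ependyma, skeletal muscle, bone and cartilage, keratinocytes, adipocytes, macrophages and microglia, lymphocytes, neutrophils, and endothelium with pericytes. Mouse genes without a symbol in human form, such as those of MHC class II, were matched to their human counterparts by hand. The counterparts of H2-Aa, H2-Ab1 and H2-Eb1 were not analysed here, so that list was tested on the remaining 4 genes.

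The genes named in the text follow a rule fixed with the lists. It takes 13 fixed genes, then per comparison up to 6 rises and 6 falls past the threshold with a mean log2 CPM of at least 1. Their sign had to hold without each library in turn, and predicted or clone names were left out. It adds up to 3 called members of each called list, and, where no gene passes, the 5 genes of smallest p as values only. Members of the lists are also given as examples of their list. Any other gene is said to have been chosen after its values were seen.

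The steps were tested on simulated counts for the 13707 genes, with 50 genes changed at each fold. Between constructs edgeR recovered 6% of genes changed 2-fold, 14% at 4-fold, 72% at 8-fold and 72% at 16-fold, with 2 false calls among 84. DESeq2 recovered 64% at 4-fold, with 90 false calls among 218. Between regions edgeR recovered 0% at 2-fold, 8% at 4-fold, 76% at 8-fold and 60% at 16-fold, with 3 false calls among 75. Camera was tested on 21 simulated lists between constructs, and it called the changed list and 0 of the others. Every gene was drawn independently in these simulations, so they cannot test the preset correlation between genes. They used edgeR's own dispersions and did not model the excess of low values in the files, so false calls there may differ.

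Settings tried beside these were DESeq2 1.42.0 (Wald test), limma-voom with sample quality weights, DESeq2 size factors in place of TMM, no low-count filter and a test against a fold change of 1.5. Others left out the region or construct term, used 1 region or 1 construct, added the replicate number as a block, or left out each library in turn. The block was fitted only to replicates 1 to 3 of each construct, with 13194 genes tested. For lists, the correlation was estimated and fry replaced camera. Added after the data were seen were limma on log2 CPM, leaving out the genes at 0 or 1 in some library and over 100 in another, the muscle list mean as a covariate, and exact permutation of the list means per library. No label says that each library came from a separate animal, and replicates 6 and 7 of YAP1-MAML2-v2 share a number in the names of their files, so p-values measure the spread between these libraries. Every column of the files was used.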

Results

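The series holds RNA-seq of meningioma-like tumors that grew in mice after delivery of 1 of 2 forms of YAP1, a transcriptional coactivator that the Hippo pathway restrains. YAP1-MAML2 joins YAP1 to MAML2, a coactivator of Notch signaling, and NLS-2SA-YAP1 is a constitutively active YAP1 according to the series title. Tumors were made with YAP1-MAML2-v2 (n = 7) and the others with NLS-2SA-YAP1 (n = 3). Labels place YAP1-MAML2-v2 replicates 1, 3, 4 and 5 and NLS-2SA-YAP1 replicates 2 and 3 in the extra cranial region. YAP1-MAML2-v2 replicates 2 and 6 and NLS-2SA-YAP1 replicate 1 are extra axial, and YAP1-MAML2-v2 replicate 7 is intra ventricular. No normal tissue or uninfected control was analysed here. Library totals ran from 28001143 in NLS-2SA-YAP1 replicate 2 to 44544314 in YAP1-MAML2-v2 replicate 7. These totals are sums of deposited values that are not plain read counts, so the depth behind them is unknown.

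The first question was whether the 2 constructs gave tumors with different expression. YAP1 itself stood at 513 ± 86.6 CPM (SD, n = 3) in NLS-2SA-YAP1 tumors and at 148 ± 16.2 CPM (SD, n = 7) in YAP1-MAML2-v2 tumors. MAML2 went the other way, with 16.4 ± 5.83 CPM (SD, n = 3) against 56.3 ± 32.8 CPM (SD, n = 7). The 2 groups did not overlap for either gene. The highest YAP1-MAML2-v2 library had 174 CPM of YAP1 and the lowest NLS-2SA-YAP1 library 421 CPM. For MAML2 the lowest YAP1-MAML2-v2 library had 30.6 CPM and the highest NLS-2SA-YAP1 library 20.8 CPM. Yap1 lies on chromosome 9 at 7931999 to 8004596 and Maml2 on chromosome 9 at 13297957 to 13709388 (mm10).

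YAP1 had a log2 fold change of 1.75 (SE 0.26), with an adjusted p of 0.0898 in edgeR over all genes tested and 0.00066 when adjusted over the list alone, the 13 genes fixed beforehand. For MAML2 the log2 fold change was -1.77 (SE 0.54), with edgeR adjusted p-values of 0.247 and 0.0547 on the same scales. An exact two-sided permutation test of either gene gave p = 0.0167, the smallest that 7 against 3 allows, and 0.109 after adjustment over the fixed genes. DESeq2 placed YAP1 past the threshold over all genes (adjusted p = 1.01e-09), as did limma-voom with sample quality weights (adjusted p = 0.0197) and edgeR without the region term (adjusted p = 0.0488). Over the settings tried its adjusted p ran from 1.01e-09 to 0.376. DESeq2 also called MAML2 (adjusted p = 0.0194, with a range of 0.0194 to 0.564 over the settings). The files do not show how much of either value is transcript of the construct.

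**Figure D1:**
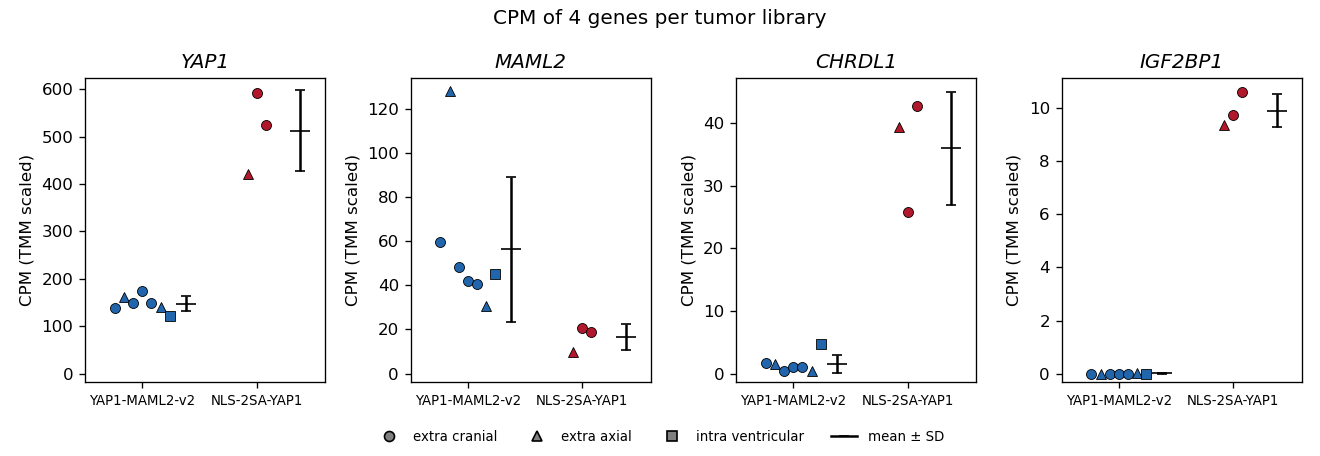
CPM of YAP1, MAML2, CHRDL1 and IGF2BP1 (vertical axes, linear) in each tumor library by construct, with the symbol giving the region and the bar the mean and SD. YAP1 was at 421 to 592 CPM in the NLS-2SA-YAP1 libraries and at 122 to 174 CPM in the YAP1-MAML2-v2 libraries.

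Over all genes, edgeR called 2 of 13707, CHRDL1 and IGF2BP1, and both rose in NLS-2SA-YAP1 tumors. CHRDL1, which encodes chordin-like 1, an antagonist of bone morphogenetic proteins, had 36 ± 8.94 CPM (SD, n = 3) against 1.54 ± 1.5 CPM (SD, n = 7). Its log2 fold change was 5.16 (SE 0.59; edgeR adjusted p = 0.0406), and its gene lies on chromosome X at 143285674 to 143394262 (mm10). IGF2BP1, which encodes an RNA-binding protein that acts on mRNA, had 9.9 ± 0.615 CPM (SD, n = 3) in NLS-2SA-YAP1 tumors, and every YAP1-MAML2-v2 library was listed at 0 or 1 (edgeR adjusted p = 0.0406). No fold is read from IGF2BP1 because of those values. Igf2bp1 lies on chromosome 11 at 95957163 to 96005940. In both genes every NLS-2SA-YAP1 library was above every YAP1-MAML2-v2 library.

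The count of called genes depended on the tool. At an unadjusted p under 0.05 edgeR had 1789 genes. DESeq2 called 685 genes (224 higher, 461 lower) and limma-voom with sample quality weights 92 (63 higher, 29 lower), each including both genes. With edgeR, both calls held without YAP1-MAML2-v2 replicate 7 (adjusted p = 0.0295) and were lost without any 1 of the other libraries. Their edgeR adjusted p then ranged up to 0.257 for IGF2BP1 and 0.227 for CHRDL1. The log2 fold change of CHRDL1 stayed between 4.94 and 5.52. Its call was also lost without the region term (4.54, edgeR adjusted p = 0.0655) and with limma on log2 CPM (5.24, adjusted p = 0.0508). In extra cranial libraries only, both calls were lost (edgeR adjusted p = 0.0976 for CHRDL1 and 0.203 for IGF2BP1). Transcripts of skeletal muscle were carried by NLS-2SA-YAP1 replicates 2 and 3 and not by replicate 1, whose CHRDL1 was 39.4 CPM. With the muscle list as a covariate, edgeR called 0 genes, with 1456 at an unadjusted p under 0.05. CHRDL1 then had a log2 fold change of 5.77 and a larger SE of 0.82 (edgeR adjusted p = 0.208), so the call ended while the difference stayed. The fitted value of IGF2BP1, which depends on values of 0 and 1 and is no measure of size, was 9.8 (SE 1.32) against 10.43 (SE 1.12) without the covariate (edgeR adjusted p = 0.208).

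Some genes just beyond the threshold were chosen after their values were seen. ANGPT2, the angiopoietin-2 ligand of the endothelial TIE2 receptor, had 5.85 ± 4.28 CPM (SD, n = 3) in NLS-2SA-YAP1 tumors and 56.3 ± 29.1 CPM (SD, n = 7) in YAP1-MAML2-v2 tumors (log2 fold change -3.32, SE 0.41, edgeR adjusted p = 0.0591). PKP2, the desmosomal protein plakophilin 2, stood at 477 ± 178 CPM (SD, n = 3) against 62.2 ± 31.2 CPM (SD, n = 7). LRP4, an LDL receptor family member, stood at 176 ± 17.5 CPM (SD, n = 3) against 42.9 ± 16.9 CPM (SD, n = 7). Their edgeR adjusted p-values were 0.0898 for PKP2 and 0.0994 for LRP4. The groups did not overlap in any of these 3 genes, which a choice by small p favors, so it is no further support.

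The YAP1 target genes showed no shift between the constructs that the tests could call. Of 22 tested members of the YAP1-TEAD list, 9 were higher and 13 lower in NLS-2SA-YAP1 tumors, and 0 passed edgeR's test over all genes or adjusted over the list alone. Camera gave the list an adjusted p of 0.978. The median log2 fold change was -0.14 in edgeR, and the limma fit under camera had a median of 0.14 and a mean of 0.08. The groups did not overlap in 3 members, which went both ways. TGFB2 had 29.2 to 52.5 CPM in NLS-2SA-YAP1 and 57.5 to 361 CPM in YAP1-MAML2-v2 tumors, LATS2 21 to 45.5 against 59.3 to 224 CPM, and PTPN14 165 to 203 against 51 to 134 CPM. Each had an edgeR adjusted p of 0.0822 over the list alone. CTGF, a secreted matricellular protein and standard YAP1 reporter, had 1210 ± 1500 CPM (SD, n = 3) against 1670 ± 1740 CPM (SD, n = 7), with single libraries between 28.7 and 5090 CPM. CYR61 had 392 ± 101 CPM against 332 ± 261 CPM, AMOTL2 164 ± 51.3 CPM against 166 ± 167 CPM, and ANKRD1 4.66 ± 1.62 CPM against 6.86 ± 11.7 CPM. Their edgeR adjusted p-values lay between 0.62 for CTGF and 0.984 for AMOTL2. The sign of CYR61, ANKRD1 and AMOTL2 turned under some settings.

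Among 24 Hippo pathway genes, 0 passed the test over all genes and 5 passed when adjusted over the list alone (edgeR). Adjustment over a list alone, here and for the lists below, does not correct for the 23 lists tested. Of all 13707 genes, 1789 had an unadjusted edgeR p under 0.05 between constructs. LATS2 passed over this list but not over the YAP1-TEAD list. AMOT, which binds YAP1, had a log2 fold change of 1.99 (SE 0.40), and TEAD4, a DNA-binding partner of YAP1, 1.83 (SE 0.49). TEAD2 of the same TEAD family had -1.70 (SE 0.38), the upstream kinase TAOK1 -1.38 (SE 0.32) and the YAP1 kinase LATS2 -1.71 (SE 0.53). NF2, the meningioma tumor suppressor that acts upstream of LATS kinases, had 38.4 ± 28 CPM (SD, n = 3) against 55.9 ± 36.1 CPM (SD, n = 7), with an edgeR adjusted p of 0.87. Camera gave the whole list an adjusted p of 0.684. The Notch list, whose pathway MAML2 serves, had 4 members higher and 10 lower, 0 called over all genes or adjusted over the list alone, and a camera adjusted p of 0.62.

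CDKN2A, for which the mice are labelled null, had values above 0 in every library, from 0.197 to 18.2 CPM, and an edgeR adjusted p of 0.761 between constructs. The labels do not say which part of the gene is missing, so these values do not check it. NES, the progenitor filament gene whose promoter drives tv-a, had 32.5 ± 40.6 CPM (SD, n = 3) against 52.1 ± 36.1 CPM (SD, n = 7), and the edgeR adjusted p was 0.735. VIM, the intermediate filament of mesenchymal cells, had 12600 ± 3460 CPM (SD, n = 3) against 6100 ± 3930 CPM (SD, n = 7), with an edgeR adjusted p of 0.476. MKI67, a proliferation marker, had 34.9 ± 13 CPM against 33.2 ± 37.5 CPM. PTGDS, the arachnoid prostaglandin D synthase, was listed at 0 in YAP1-MAML2-v2 replicate 5 and stood between 127 and 8540 CPM elsewhere. SSTR2, the somatostatin receptor used to diagnose meningioma, was listed at 0 in 5 libraries and reached 1090 CPM in YAP1-MAML2-v2 replicate 7. The edgeR adjusted p-values of MKI67, PTGDS and SSTR2 were 0.756, 0.998 and 0.916, and the signs of these 3 genes and of NF2 turned under some settings.

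Camera called 2 of 23 lists between constructs. At least 2 lists were also called in 43 of 45 splits of the libraries within regions. Camera's adjusted p-values at the preset correlation can therefore not be taken at face value here. The hypoxia list fell in NLS-2SA-YAP1 tumors, with 12 of 12 members lower, a mean log2 fold change of -1.87 and a camera adjusted p of 7.68e-06. With an estimated correlation camera gave p = 0.0449 and an adjusted p = 0.945. Without 1 library the mean log2 fold change ranged from -2.36 to -1.19, the latter without NLS-2SA-YAP1 replicate 2 (camera adjusted p = 0.000922). Its mean log2 CPM was 4.19 ± 1.1 (SD, n = 3) against 5.8 ± 0.96 (SD, n = 7). By edgeR 0 members passed over all genes and 2 when adjusted over the list alone. These were the vasodilator peptide gene ADM, with a log2 fold change of -2.63 (SE 0.59), and PDK1, a kinase that limits pyruvate oxidation, with -1.91 (SE 0.51). Exact permutation of the library means gave p = 0.05, and 0.95 after adjustment over the lists. The smallest p that 7 against 3 libraries allows is 0.0167, so a lone list among 23 could not pass after adjustment.

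The skeletal muscle list rose in NLS-2SA-YAP1 tumors by camera (adjusted p = 0.00125, mean log2 fold change 2.23, 10 of 11 members higher). With an estimated correlation its camera adjusted p = 0.945. The mean log2 fold change was 3.49 without NLS-2SA-YAP1 replicate 1 and 1.29 without replicate 3. The adjusted p was 0.172 without NLS-2SA-YAP1 replicate 3 and 0.0663 without the genes at 0 or 1 in some library and over 100 in another. By edgeR 0 members passed over all genes or adjusted over the list alone. The list was carried by single tumors: TNNT3, a fast-muscle troponin, had 62.1 and 222 CPM in NLS-2SA-YAP1 replicates 2 and 3 and 42 CPM in YAP1-MAML2-v2 replicate 3. It had at most 0.927 CPM in each of the other libraries.

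The remaining 21 lists had camera adjusted p-values of 0.248 to 0.978 and no member past edgeR's threshold over all genes. The cell cycle list (0.248, 22 of 29 members higher) and the AP-1 list (0.251, 9 of 12 lower) were among the smallest, with the neuron list (0.248). Adjusted over the list alone, edgeR called FOSL2 and IER2 of the AP-1 list, both lower in NLS-2SA-YAP1 tumors, AQP1 of the choroid plexus and ependyma list, and OGN of the meningeal fibroblast list, both higher. OGN, the small leucine-rich proteoglycan osteoglycin, stood at 4490, 4540 and 5000 CPM in the NLS-2SA-YAP1 libraries and at 247 to 2370 CPM in the others. The meningioma marker list had 0.35, the choroid plexus and ependyma list 0.35 and the oligodendrocyte list 0.453. Collagens, type I interferon and keratinocyte lists had 0.643, and meningeal fibroblast, MHC class II and endothelial lists 0.684. Macrophage and microglia genes had 0.709, neutrophil genes 0.776, bone and cartilage genes 0.852, astrocyte and adipocyte genes 0.858 and lymphocyte genes 0.978. In the YAP1-TEAD, type I interferon and lymphocyte lists edgeR's median was negative, while limma's median and mean and camera's direction were positive. In the astrocyte list both medians and the mean were negative, while camera's direction against other genes was positive.

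**Figure D2:**
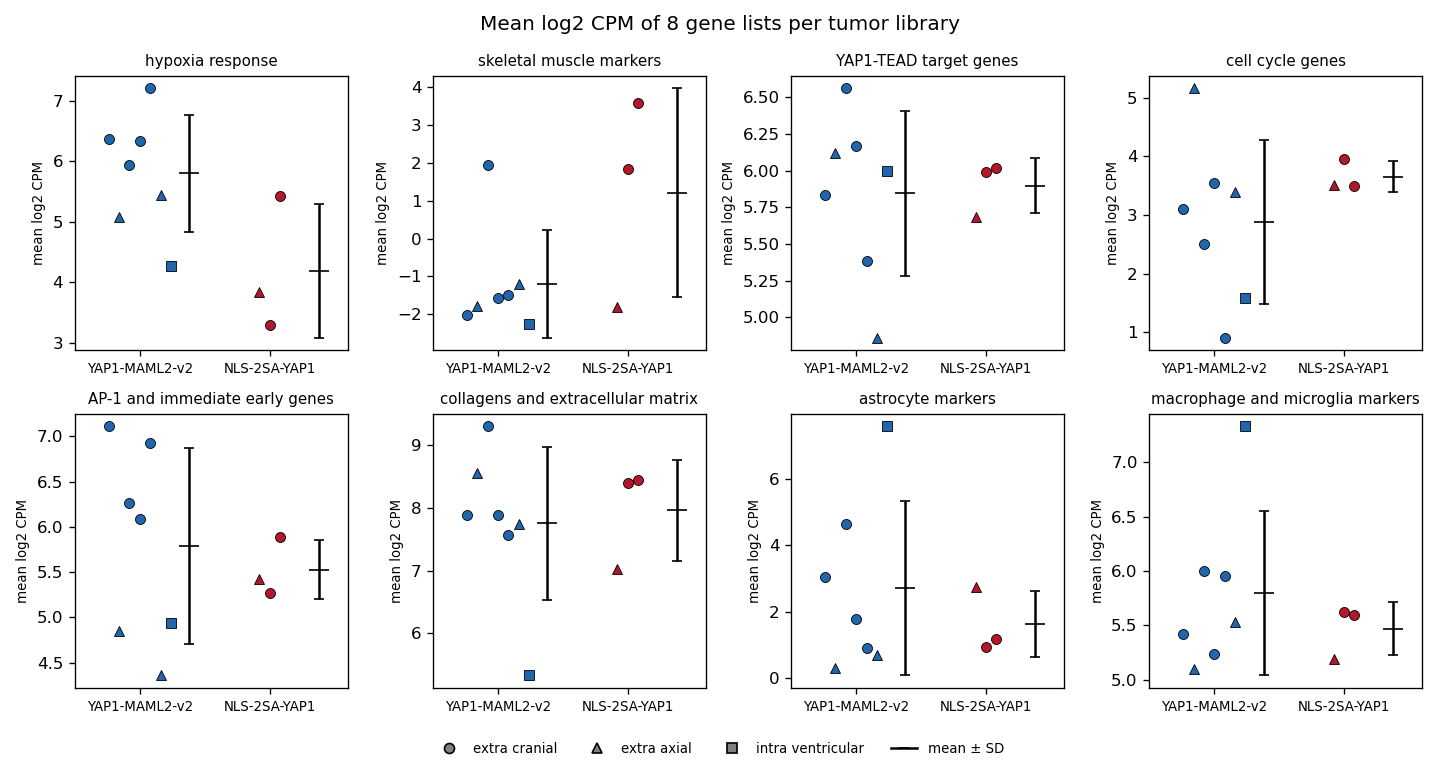
Mean log2 CPM of 8 fixed gene lists (vertical axes) in each tumor library by construct, with the symbol giving the region and the bar the mean and SD. The hypoxia list was at 4.19 ± 1.1 in NLS-2SA-YAP1 and 5.8 ± 0.96 in YAP1-MAML2-v2 tumors, and the astrocyte and macrophage lists were highest in the intra ventricular tumor.

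The second question was how extra axial tumors (n = 3) differed from extra cranial ones (n = 6). Cell cycle genes were higher in the extra axial tumors in 29 of 29 members, and AP-1 and immediate early genes were lower in 11 of 12. Muscle genes were lower in 10 of 11 and hypoxia genes in 10 of 12. Members of a list can vary together and are not replicates. Among lists that camera did not call, neuron genes were lower in 8 of 8 members. Type I interferon genes, also not called, were higher in 13 of 14. No single gene passed edgeR's test, with 413 at an unadjusted p under 0.05. DESeq2 called 31 genes (3 higher, 28 lower) and limma-voom with sample quality weights 0. Camera called 7 of 23 lists, and 14 of 45 splits of region within constructs gave at least 7. The number of called lists therefore does not exclude chance.

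The cell cycle list rose in extra axial tumors by camera (adjusted p = 5.22e-10), a call lost with an estimated correlation (adjusted p = 0.619). It had a mean log2 CPM of 4.02 ± 0.99 (SD, n = 3) against 2.92 ± 1.1 (SD, n = 6). Within NLS-2SA-YAP1 the extra axial library (3.51) lay between the extra cranial ones (3.96 and 3.49). Within YAP1-MAML2-v2 the extra axial libraries had 5.16 and 3.39, and the extra cranial ones 0.91 to 3.55. MKI67 had 61.2 ± 45.5 CPM (SD, n = 3) against 24.4 ± 15.1 CPM (SD, n = 6), an edgeR log2 fold change of 1.6 (SE 0.71) and an adjusted p of 1. That fold was 0.78 without YAP1-MAML2-v2 replicate 2 and 2.38 without NLS-2SA-YAP1 replicate 1. UBE2C, a ubiquitin-conjugating enzyme of mitosis, had a log2 fold change of 2.19 (SE 0.89), with 15.4 CPM in YAP1-MAML2-v2 replicate 2. That tumor had the highest list mean, 5.16, and without it the camera adjusted p was 0.13 with a mean log2 fold change of 0.36. The mean log2 fold change was 1.1 with every library, 0.71 without YAP1-MAML2-v2 replicate 5 and 1.74 without NLS-2SA-YAP1 replicate 1.

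The AP-1 and immediate early list fell in extra axial tumors (camera adjusted p = 4.03e-06), with a mean log2 CPM of 4.88 ± 0.53 (SD, n = 3) against 6.26 ± 0.68 (SD, n = 6). With an estimated correlation the adjusted p was 0.342. JUNB had a log2 fold change of -2.49 (SE 0.80) and FOSL2 -1.35 (SE 0.44), and neither passed edgeR's test. FN1, which encodes fibronectin, had -1.72 (SE 0.75), and LOX, a collagen cross-linking oxidase, -2.20 (SE 0.73). Their list of collagens and matrix genes fell by camera (adjusted p = 0.0452, 18 of 21 members lower), and with an estimated correlation the adjusted p was 0.675. Its direction against other genes turned without NLS-2SA-YAP1 replicate 1 (adjusted p = 0.65), and the call was lost without YAP1-MAML2-v2 replicates 3 or 6 (0.271 and 0.136) or NLS-2SA-YAP1 replicates 2 or 3 (0.133 and 0.173). Its mean log2 fold change of -0.47 was -0.86 without YAP1-MAML2-v2 replicate 2, -0.26 without YAP1-MAML2-v2 replicate 3 and -0.03 without NLS-2SA-YAP1 replicate 1.

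The other 4 called lists fell too. Hypoxia genes had a camera adjusted p of 3.42e-05 and muscle genes 2.98e-06, while MHC class II genes and macrophage and microglia genes both had 0.0452. With an estimated correlation the adjusted p-values were 0.619, 0.619, 0.63 and 0.619 in that order. A replicate block was fitted only to replicates 1 to 3 of each construct. With it the hypoxia call was lost (mean log2 fold change -0.37, camera adjusted p = 0.284), as were those of the macrophage list (0.249) and of the collagens (0.356). Without YAP1-MAML2-v2 replicate 2 the mean log2 fold change of the MHC class II list was 0.15 (camera adjusted p = 0.681). That call was also lost without YAP1-MAML2-v2 replicates 1, 3, 4 or 5 or NLS-2SA-YAP1 replicate 3 (0.0865 to 0.142), and the mean was -1.78 without YAP1-MAML2-v2 replicate 6 and -1.6 without NLS-2SA-YAP1 replicate 1, against -1.02 with every library. The macrophage and microglia call was lost without YAP1-MAML2-v2 replicates 2, 3 or 5 or NLS-2SA-YAP1 replicates 1 or 2 (0.0822 to 0.276). Muscle transcripts stood in extra cranial tumors, namely YAP1-MAML2-v2 replicate 3 and NLS-2SA-YAP1 replicates 2 and 3, and the muscle call was lost without YAP1-MAML2-v2 replicate 3 (0.123) or NLS-2SA-YAP1 replicate 1 (0.298), with a mean log2 fold change of -1.24 and -0.72 against -1.98 with every library. Without YAP1-MAML2-v2 replicate 3 camera called 3 lists. By edgeR 0 members of the 7 lists passed over all genes, and adjusted over the list alone only ADM of the hypoxia list passed. The remaining 16 lists had camera adjusted p-values from 0.0947 to 0.853. The oligodendrocyte, type I interferon and lymphocyte lists had an edgeR median opposite in sign to limma's median and mean and to camera's direction. In the meningeal fibroblast, meningioma, keratinocyte, and choroid plexus and ependyma lists limma's median and mean differed in sign.

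The 5 genes of smallest p between regions are given as values only. TVP23B, a Golgi membrane protein gene, had 11.9 ± 1.13 CPM (SD, n = 3) in extra axial and 65.4 ± 25.8 CPM (SD, n = 6) in extra cranial tumors, with a log2 fold change of -2.40 (SE 0.36) and an edgeR adjusted p of 0.895. Tvp23b lies on chromosome 11 at 62879455 to 62916780 (mm10). FAM20A had 47.8 ± 21.5 CPM against 255 ± 72 CPM. TFPI, the tissue factor pathway inhibitor, had 1.79 ± 1.35 CPM against 32 ± 26.7 CPM, and ADM had 11.1 ± 11 CPM against 56 ± 40.9 CPM. UNC5CL had 0.574 to 0.97 CPM in the extra axial tumors and was listed at 0 or 1 in the extra cranial ones. The edgeR adjusted p of these last 4 genes was 1. All 5 genes were among the 31 that DESeq2 called (adjusted p from 4.85e-08 for TVP23B to 0.0356 for UNC5CL). In the simulation of this comparison DESeq2 made 95 false calls among 225. That simulation used edgeR's dispersions and did not model the excess of 0 and 1, so its share need not hold for these genes. The groups did not overlap in TVP23B, FAM20A, TFPI and UNC5CL, which a choice by small p favors, so it is no further support. CTGF had 443 ± 403 CPM (SD, n = 3) against 2240 ± 1740 CPM (SD, n = 6), with a log2 fold change of -2.77 (SE 1.06) and an edgeR adjusted p of 1. The 13 fixed genes all had an adjusted p of 1 and at least 0.307 when adjusted over the list alone.

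The third question was whether the construct difference depended on region. The interaction called 1 gene of 13487 by edgeR, GABRB2, which encodes a subunit of the GABA-A receptor (adjusted p = 0.0161), with 963 genes at an unadjusted p under 0.05. GABRB2 lay outside the naming rule. In extra cranial tumors it had 19.1 to 31.2 CPM with YAP1-MAML2-v2 and was listed at 0 or 1 with NLS-2SA-YAP1. In extra axial tumors it was listed at 0 or 1 with YAP1-MAML2-v2 and had 12.7 CPM in the lone NLS-2SA-YAP1 library, which is assumed to vary like the others. The call therefore depends on 1 library and on values of 0 and 1, and no effect of region on the constructs is read from it. The call was lost with limma-voom (adjusted p = 0.14) and without YAP1-MAML2-v2 replicates 2, 3 or 6 or NLS-2SA-YAP1 replicates 2 or 3, where the edgeR adjusted p ranged from 0.063 to 0.236. DESeq2 called 204 genes and limma-voom 0.

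The intra ventricular tumor, YAP1-MAML2-v2 replicate 7, has no replicate and is described by values alone. The astrocyte, neuron and macrophage lists had their highest means there. GFAP, the astrocyte filament, had 1200 CPM against at most 39.9 CPM elsewhere, and the water channel AQP4 had 103 CPM against at most 25.6 CPM. The astrocyte list had a mean log2 CPM of 7.6, which was 2.95 above the highest of the other YAP1-MAML2-v2 tumors. The neuron list was 2.97 above the highest of these tumors and the macrophage and microglia list 1.33 above. The microglial receptor P2RY12 had 163 CPM against at most 6.95 CPM elsewhere. The meningioma marker list had a mean log2 CPM of 8.96 against at most 7.43 elsewhere, in NLS-2SA-YAP1 replicate 3. Of its 8 tested members, only PTGDS (8540 CPM) and SSTR2 (1090 CPM) were at their highest in the intra ventricular tumor. VIM of the same list was at its lowest there, with 1920 CPM against 3130 to 16600 CPM elsewhere. PTGDS and SSTR2 are among 4 members listed at 0 or 1 in some library, so the list mean depends in part on such values. Collagens and matrix genes were lower than in any other library, with a list mean of 5.33, and POSTN, the matrix protein periostin, had 0.0474 CPM against 14.7 to 238 CPM elsewhere.

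**Figure D3:**
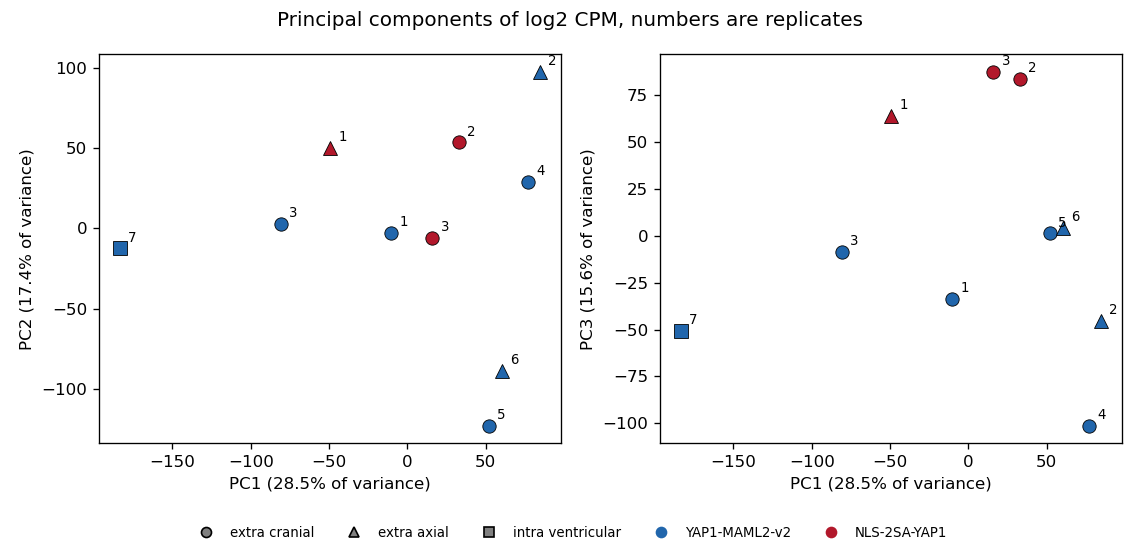
Principal components of log2 CPM over the tested genes, with PC1 (28.5% of variance) against PC2 (17.4%) and PC3 (15.6%); colors give the construct, symbols the region and numbers the replicate. The intra ventricular tumor has the lowest PC1, -183.5, and the NLS-2SA-YAP1 tumors have PC3 scores of 63.8 to 87.2, above the YAP1-MAML2-v2 tumors, whose highest score is 4.

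Within each library, the YAP1-TEAD targets ranked in the upper part of the tested genes. The median of the list lay between the percentiles 68.1 and 88.2 of the library, the lowest and the highest tumor. Meningioma markers lay between 88.4 and 98.1, collagens and matrix genes between 78.6 and 98.6, and Hippo genes between 63.5 and 82.9. Cell cycle genes ranged from 13.1 to 57.3. Muscle genes stayed between 2.4 and 26.8 and oligodendrocyte genes between 5 and 21.2. These ranks compare different genes, in values that are not plain read counts, and have no normal tissue beside them.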

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

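The tests of why values stand at 0 or 1, apart from the test of a difference between the constructs, were chosen only after the result was seen.

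In 44 sets of the 7 YAP1-MAML2-v2 libraries, a library was looked for whose gap to the nearest other, divided by the whole range, was above Dixon's critical value for 7 values, and 7 sets had one. For independent sets of normally distributed values, chance alone gives about 1 such library in 20 sets. These sets share the same 7 libraries and some hold values of 0 or 1, so the 7 found cannot be set against that rate. The intra ventricular tumor, replicate 7, stood above the others in the meningioma marker list (mean log2 CPM 8.96, next 6.67) and in the macrophage and microglia list (7.33, next 6). It stood below them in FAM20A (1.01, next 5.89). Replicate 3 was above the others in the skeletal muscle list (1.94, next -1.19), and replicate 2 was below them in the MHC class II list (3.89, next 6.41). PTGDS stood at a log2 CPM of -4.19 in replicate 5, where it is listed at 0, and the next library was at 6.99. IGF2BP1 was at -3.59 in replicate 6 and at -4.19 in the others, which is a single value of 1 among values of 0. The interaction test singled out GABRB2, whose construct difference in extra axial minus extra cranial tumors was fitted at a log2 of 20.07. That number depends on values of 0 and 1 and is no measure of size.

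Genes that are abundant in most tumors stand at exactly 0 or 1 in others, PTGDS and GABRB2 among them. Reads counted from the libraries as sequenced would keep the number of 1s squared, over 2 times the 0s times the 2s, at or below 1. It was 4.55 (bootstrap 95% interval 2.77 to 8.59), which argues against plain read counts. Of the values from 0 to 9 in these genes, 84.1% (80.8 to 87) were 0 or 1, which restates the pattern and is no separate test of its source. An adjustment after counting that left 0 and 1 as they were may have made the pattern. A difference between the constructs stays open, since 4 of 45 splits of the libraries had at least as many genes with such values in 1 construct (760 genes, highest other split 880), and the bound written beforehand would have excluded it although a share over 0.05 excludes nothing, so that reading was set after the value was seen.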

How the results depend on the processing

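Settings chosen only after the data were seen were limma on log2 CPM, leaving out genes at 0 or 1 in some library and over 100 in another, the muscle covariate and the exact permutation of list means. Over named genes and called lists, 702 values kept direction and side of the threshold, 84 lost the threshold, 12 gained it and 63 turned direction. The cause of the changes was not tested. Depth behind the deposited values, which are not plain read counts, is unknown, so its limits cannot be given.

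Between constructs edgeR called 2 genes. DESeq2 called 685, limma-voom with sample quality weights 92, limma on log2 CPM 4, edgeR with no low-count filter 4, without the genes at 0 or 1 in some library 1 (CHRDL1), without region term and intra ventricular library 15, and in extra cranial libraries only 4, none of them shared. CHRDL1 lost its call without the region term (4.54, adjusted p = 0.0655) and with limma (5.24, 0.0508). With the muscle covariate edgeR called 0 (1456 at an unadjusted p under 0.05), while the fitted log2 fold changes were 5.77 for CHRDL1 (5.16 without it) and 9.8 for IGF2BP1 (10.43), with larger SEs. Without 1 library it called 0 to 2, with 1093 to 1959 at an unadjusted p under 0.05. Between regions edgeR called 0 (413 unadjusted), DESeq2 31, limma-voom and limma 0, and edgeR without 1 library 0 to 1. For the interaction edgeR called 1, DESeq2 204, limma-voom 0 (1075 unadjusted), limma 4, edgeR without the genes at 0 or 1 in some library 0 (776 unadjusted) and without 1 library 0 to 3.

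Camera called 2 lists between constructs. An estimated correlation, fry and exact permutation of list means each gave 0 (with 1, 2 and 0 at an unadjusted p under 0.05), extra cranial libraries only 6, leaving out the genes at 0 or 1 in some library 1, and leaving out 1 library 1 to 6. In either comparison, exact permutation of so few libraries could hardly pass after adjustment over the lists, so its count of 0 decides little. Between regions camera called 7 lists. An estimated correlation, fry and exact permutation each gave 0 (each with 1 unadjusted), and leaving out 1 library gave 3 to 9. With no low-count filter camera called 5, without the collagen and MHC class II lists (adjusted p = 0.0567 for both). In YAP1-MAML2-v2 libraries only it called 6, without the macrophage (-0.41, 0.166), muscle (-0.72, 0.335) and collagen (0.709) lists and with the neuron and astrocyte lists.

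Replicate numbers 1 to 3 are shared by both constructs. Deviations of same-numbered libraries correlated at 0.167, 0.337 and -0.072. No other pairing was set beside these values, so they do not settle whether the numbers pair the samples. A replicate block was fitted only to the libraries with these numbers, which left 13194 genes and hardly any libraries beyond the terms fitted. Its counts are therefore no like-for-like check on the main fit. With the block edgeR called 36 genes between constructs and 6 between regions, and camera 5 lists between constructs and 6 between regions. Of those 6, 4 were among the 7 lists called without the block. The hypoxia (-0.37, adjusted p = 0.284), collagen (-0.35, 0.356) and macrophage (-0.38, 0.249) calls were lost, and type I interferon and lymphocyte lists were gained. The block also turned CYR61 (-0.01), AMOTL2 (0.34), PTGDS (-0.36) and MKI67 (-0.1) between constructs, and CYR61 (0.08) and VIM (0.32) between regions. SSTR2 passed the threshold under the block in both comparisons (edgeR adjusted p = 0.00643 and 0.000846, highest over the settings 0.999 and 1). SSTR2 is listed at 0 in 5 libraries, so no fold is read from it.

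None of the other turned genes passed the edgeR threshold. Between constructs the log2 fold changes turned in extra cranial libraries only for CYR61 (-0.15), ANKRD1 (-1.17), AMOTL2 (0.18) and PTGDS (-2.29). Without the region term they turned for ANKRD1 (-0.56), PTGDS (-0.84) and SSTR2 (-1.06), and without region term and intra ventricular library for ANKRD1 (-0.78) and MKI67 (-0.11). AMOTL2 turned with limma-voom (0.89), limma (0.51) and the muscle covariate (0.49), MKI67 with the muscle covariate (-0.17) and PTGDS without a low-count filter (-0.01). Without 1 library the ranges were -1.01 to 0.06 for NF2, -0.14 to 1.14 for CYR61, -1.17 to 1.92 for ANKRD1, -0.41 to 0.79 for AMOTL2, -2.29 to 1.41 for PTGDS and -1.93 to 10.11 for SSTR2.

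Between regions limma-voom turned MAML2 (-0.24), CDKN2A (-0.7), NES (-0.66) and AMOTL2 (-0.15), and limma turned MAML2 (-0.06) and CDKN2A (-0.35). In YAP1-MAML2-v2 libraries only, CDKN2A (-0.9), NES (-1.32), PTGDS (-1.84) and the collagen and matrix list against other genes (-0.03) turned, and without the construct term CDKN2A (-0.2) and NES (-0.14). Without 1 library the ranges were -0.82 to 0.72 for MAML2, -0.9 to 1.26 for CDKN2A, -1.32 to 1.62 for NES, -1.12 to 1.06 for AMOTL2, -1.84 to 1.97 for PTGDS, -1.88 to 10.12 for SSTR2, -0.86 to -0.03 for the collagen and matrix list and -1.78 to 0.15 for MHC class II.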

Other observations

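Tests chosen only after the result was seen were the ratio of YAP1 to MAML2, the comparison of hypoxia genes within the extra cranial region and the choice of the tumor described first.

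YAP1-MAML2-v2 replicate 2, an extra axial tumor, had the highest cell cycle list and the lowest type I interferon, MHC class II and lymphocyte lists. Its cell cycle list had a mean log2 CPM of 5.16 and MKI67 stood at 110 CPM. The type I interferon list had a mean of 1.07 and the lymphocyte list -2.23, both the lowest of the 10 libraries. The macrophage and microglia list was the lowest too, by little (5.1, next 5.19). The neutrophil list did not follow them, with 0.53 in a range of -1.81 to 0.79. Replicate 2 also had the highest Hippo list (6.54) and the lowest astrocyte list (0.3). CD74, the MHC class II invariant chain, had 151 CPM against 456 to 2150 CPM elsewhere, and the interferon-induced gene IFIT1 had 2.15 CPM against 24.2 to 123 CPM. Replicate 6, the other extra axial YAP1-MAML2-v2 tumor, had the highest interferon list (5.92) and lymphocyte list (2.74) of the libraries. These are values of single tumors, and no explanation was tested.

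KRT18, an epithelial keratin on the meningioma marker list, had 134 to 289 CPM in YAP1-MAML2-v2 replicates 4, 5, 6 and 7 and was listed at 0 or 1 in the other libraries. SLC47A1, an arachnoid barrier transporter, reached 5540 CPM in NLS-2SA-YAP1 replicate 3 and was listed at 0 or 1 in 5 libraries. The desmosomal gene DSP had 7320 CPM in NLS-2SA-YAP1 replicate 2 and was listed at 0 in replicate 1. All 3 genes were chosen after their values were seen.

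YAP1 and MAML2 values separated the constructs. In the log2 ratio of YAP1 to MAML2, 0 libraries lay on the other construct's side, which follows from the separation of both genes and is no test of the labels, a reading set after the values were seen. The ratio was 0.32 to 2.14 in YAP1-MAML2-v2 and 4.67 to 5.16 in NLS-2SA-YAP1 libraries. Transcript of the delivered constructs, counted on the mouse genes, may add to both values, and this cannot be told apart from a change of the mouse genes. Among the paralogs WWTR1, MAML1 and MAML3 the largest absolute log2 fold change was 1.44, for MAML3 (-1.44, SE 0.51), which is within the errors of MAML2 (-1.77, SE 0.54), a reading of the errors set after the values were seen.

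The hypoxia list was lower in NLS-2SA-YAP1 tumors by -1.87 (SE 0.53) in its mean. With the muscle list as a covariate the difference was -1.75 (SE 0.72). It kept most of its size, but its SE grew and few libraries were left to measure it, so muscle tissue is not excluded. Within the extra cranial region the highest NLS-2SA-YAP1 mean minus the lowest YAP1-MAML2-v2 mean was -0.51. Region does not account for the difference among these few libraries, where separation by chance is not excluded. Over all regions the groups overlapped, with 5.42 in NLS-2SA-YAP1 replicate 3 and 4.27 and 5.08 in YAP1-MAML2-v2 replicates 7 and 2. Over the 11 of 12 members without values kept at 0 or 1, the median edgeR log2 fold change was -1.56. The fall was therefore not confined to members with such values. Leaving out so few members could hardly move the median, so this is no further test of those values. A biological difference between the constructs stays open as a hypothesis, as does tumor size or time of collection, which the labels do not give, and the number of called lists does not exclude chance.

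The constructs were also set against other splits of the libraries within regions. At least 2 genes were called in 14 of 45 splits (highest other 26), so chance is not excluded for the 2 called genes. A split with several times the real count may come from a structure of the samples or from chance, which were not told apart. The count of genes at an unadjusted p under 0.05 was reached in 1 of 45 splits, the real one (1789, highest other 1730). That share is under 0.05, which argues against chance for that count alone, by a small margin over the next split. It is 1 of 6 counts tested in this way here, beside the count of genes with values of 0 or 1 in 1 construct. Without NLS-2SA-YAP1 replicate 2 the real count of genes at an unadjusted p under 0.05 was 1093. At least 2 lists were called in 43 of 45 splits (highest other 12). Nearly any split thus called as many lists as the real one, so the number of called lists is no evidence of a construct difference. Between regions the count of genes called by edgeR was 0, which all 45 splits reach by construction (highest other 53), so this says nothing of chance, a reading set after the value was seen. The split with 53 may likewise come from a structure of the samples or from chance, which was not tested. Of the splits, 30 gave at least the 413 genes at an unadjusted p under 0.05 (highest other 1842) and 14 gave at least 7 lists (highest other 11). Chance is not excluded for these last counts.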
